A study of Mus musculus with 8 samples.

How the data were processed

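Atherosclerotic lesions of the mouse brachiocephalic artery, the short vessel that leaves the aortic arch and is a common site for studying advanced plaques, were profiled by RNA sequencing. Per the labels, the tissue was flash frozen, RNA was taken with Trizol, total RNA was used, libraries followed standard Illumina protocols, and the mice were C57BL/6 animals that had been on a Western diet for 18 weeks. Per the series' design text, the mice were wild type for the smooth muscle lineage tracing line, were sequenced on a HiSeq instrument, and were given an antibody against interleukin-1β (IL-1β) or control immunoglobulin G (IgG), with 4 animals per group. The labels give no other genotype. Each of the 8 libraries is therefore 1 animal, and group membership was taken from the sample titles.

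The values used are raw counts, deposited as 1 table of reads per gene symbol for the 8 libraries, together with a table of alignments by status. Per the file headers, the authors counted reads over exons with featureCounts 1.4.6-p4 and grouped exons by gene name in the UCSC annotation of the mm9 build. The header shows no option for strand, for read pairs or for reads with several alignments. In the status table, alignments at several places and reads over more than 1 gene are unassigned classes, so they are left out of the counts. Near-identical copies and overlapping genes are therefore counted from their remaining reads only, and reads from an antisense transcript over an exon count for the gene of that exon. Per the submitters' processing notes, CASAVA, STAR 3.0, Subread and DESeq2 were also used, with no role given for each. The exon length that the deposited table gives in bases is the authors' value for each gene and entered no test. The alignment status table gave the shares of alignments that were assigned, multimapping, without a feature or ambiguous, and entered no gene test. Coordinates below are those of the deposited table (mm9); the reference annotation supplied with a later build was not used here. The table holds 24391 gene symbols, of which 2802 had no count in any library, and no mitochondrially encoded gene. Every column of per-sample values was used.

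Counts assigned to genes ranged from 20137336 to 29453014 per library. Genes were kept by the edgeR filterByExpr rule on group, with its minimum count of 10 and minimum total count of 15, which left 15980 genes. Library sizes were scaled by trimmed mean of M values (TMM). The comparison of antibody against IgG was fitted with the edgeR quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3, robust=TRUE), with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes kept, with a threshold of 0.05. Standard errors were derived from the log2 fold change and the F statistic of the same test, and 95% intervals from its degrees of freedom. Positive log2 fold changes mean higher in antibody-treated animals. Expression is given as CPM from TMM-scaled library sizes, with group means given with the SD over 4 animals.

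Before the data were examined, 32 gene lists were fixed: smooth muscle contractile and modulated smooth muscle genes, collagens and matrix, matrix proteases, macrophage, foam cell and lipid handling, alternative macrophage, classical macrophage, IL-1 ligands and receptors, IL-1 and NF-kB targets, proliferation, interferon response, immediate early and handling, cholesterol synthesis, unfolded protein response and mitochondrially encoded genes, plus markers of other cells the sample could hold. These were neutrophil, T cell, thymocyte, B and plasma cell, antigen presentation and dendritic, mast cell, endothelial, adventitial fibroblast, white adipocyte, brown adipocyte, skeletal muscle, cardiac muscle, cartilage and bone, nerve and Schwann, erythroid, and epithelial and thyroid lists. Of 406 different list genes, 396 were in the table, with Ccn2 taken under its older symbol Ctgf, and 31 lists had at least 3 genes kept; the mitochondrial list had 0 and was not tested. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, against all other genes, and adjusted over the 31 lists. The same test with an estimated correlation, and fry in its directional and mixed forms, were run beside it. A list score, the mean log2 CPM of the kept members in each animal, was compared between groups with a two-sided exact permutation test over 70 assignments, for which the smallest possible p is 0.0286.

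The genes named in the text follow a rule fixed at the same time: up to 12 genes per direction with the smallest p among those past the threshold, or, where fewer than 5 passed in a direction, the 5 with the smallest p as values that did not pass; a panel of 13 genes (Il1b, Il1a, Il1r1, Il1rn, Il6, Acta2, Myh11, Col1a1, Col3a1, Cd68, Lgals3, Arg1 and Mrc1); and up to 4 members per list with the smallest p. Symbols without a given name (Gm, Rik and LOC models) were counted but not named. Transcripts of Xist, Ddx3y, Eif2s3y, Kdm5d and Uty were read as a check of sex.

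The scripts were tested on simulated data first. Counts of 15851 kept genes were drawn from the means, dispersions and library sizes of these libraries, with 200 genes changed and 1 list changed by 1.5-fold. The test called 16.3% of genes changed 1.5-fold, 54% of those changed 2-fold, 88% of those changed 4-fold and 98.0% of those changed 8-fold; 9 of its 138 calls were genes that had not been changed. The changed list ranked first, and 0 other lists passed. Each gene was drawn on its own, so the simulated lists held no correlation between their members. In the real libraries the estimated correlation had a median of 0.443 over lists. The simulated run therefore does not show how the list test behaves on such lists.

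Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom with sample quality weights, other size factors, other filters on low counts, other dispersion and threshold settings, the replicate number or the earlier and later replicates as a block, 1 surrogate variable (sva 3.50.0), a score of other tissues as a covariate, other set tests, and each animal left out in turn. A fit without IgG animal 2 and antibody animal 3, and a fit with the macrophage score as a covariate, were added after the data had been seen. Principal components were taken from centred log2 CPM of the kept genes.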

Results

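The samples were 8 brachiocephalic artery lesions from mice kept on a Western diet for 18 weeks, 4 from animals given an antibody against IL-1β, a cytokine made mainly by activated macrophages, and 4 from animals given IgG as a control. Counts assigned to genes were 28747515, 21902802, 29107018 and 29453014 in IgG animals 1 to 4 and 20137336, 27100415, 23875337 and 24539280 in antibody animals 1 to 4. No difference between the groups was detected in assigned counts (exact permutation test, two-sided, p = 0.229) or in the share of alignments assigned (31.4% ± 4.76 in IgG and 31.2% ± 2.94 in antibody animals, SD, n = 4 each, exact permutation p = 0.886). The multimapping share was 40.7% ± 4.95 and 38.9% ± 3.54 (exact permutation p = 0.629). Counts of the Y-linked gene Ddx3y lay between 2732 and 5459 in every library and those of Xist between 6 and 36. The ribosomal precursor transcript Rn45s took 1.76% to 7.12% of counts. No pair of libraries agreed within counting noise: the lowest chi-square per degree of freedom of any pair was 27.9.

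The comparison of antibody with IgG asks what neutralising IL-1β changes in an advanced lesion. The single-gene calls depended on the tool, and the genes with the smallest p had separate group values. Among these, Sugct, which encodes a mitochondrial CoA transferase, had 1.03 ± 0.149 CPM in IgG and 3.61 ± 0.731 CPM in antibody animals (SD, n = 4), and Polr2k, a small subunit shared by RNA polymerases, had 5.57 ± 0.929 and 13.3 ± 1.62 CPM. Dcstamp, which encodes a protein needed for fusion of osteoclasts and macrophage giant cells, had 13.2 ± 7.54 CPM in IgG and 1.87 ± 0.407 CPM in antibody animals. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 of 15980 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.208. At an unadjusted p under 0.05 there were 509 genes, 180 higher and 329 lower with the antibody, where chance alone gives about 799. That count and its balance depend on single animals: 1517 genes without IgG animal 1 (57.4% higher), 783 without antibody animal 2 (54.9% higher), 310 without IgG animal 4 and 336 without antibody animal 3. They also depend on the method, with 565 genes in DESeq2, 2772 in limma-voom, and 53.1% higher with total-count scaling against 35.4% with TMM.

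DESeq2 called 8 genes and limma-voom with sample quality weights called 2. The 8 were Sugct, Polr2k and Gpr137b-ps, which were higher, and Hist1h4i, Dcstamp, H2-Ob, Lst1 and Wfdc2, which were lower; limma-voom called Sugct and Polr2k. With edgeR and 1 animal left out, Gpr137b-ps passed without IgG animal 1 (adjusted p = 0.0468) and Hist1h4i without antibody animal 2 (adjusted p = 0.0112). In the edgeR fit none of these passed, so the values that follow did not pass there. The log2 fold changes were 1.80 ± 0.23 (SE) for Sugct, 1.25 ± 0.17 for Polr2k and 1.26 ± 0.24 for Gpr137b-ps. Rgs9bp, an anchor of a G-protein regulator, had 0.98 ± 0.21, and Rnf222, a ring finger protein gene at 0.0694 CPM in IgG animals, with no count in IgG animals 2 and 4, had 5.40 ± 1.14. Lower values were -2.81 ± 0.42 for Dcstamp, -1.19 ± 0.22 for H2-Ob, a chain of the class II peptide-loading regulator, -1.86 ± 0.34 for the histone H4 gene Hist1h4i, -0.80 ± 0.16 for the leukocyte gene Lst1 and -3.76 ± 0.79 for Wfdc2, which encodes a secreted epithelial protein. For each of these 10 genes the 4 antibody values and the 4 IgG values did not overlap, as follows from choosing the smallest p; over all genes 314 had groups that did not overlap, where chance (2.86% of genes) gives about 457. Gpr137b-ps is a pseudogene and Hist1h4i one of many near-identical histone genes, so their levels are uncertain: reads shared with a copy were left out, and only uniquely placed reads are counted.

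These 10 genes lie on 6 chromosomes of mm9. Gpr137b-ps (chromosome 13, 12706333 to 12742662), Sugct (chromosome 13, 16949310 to 17786599) and Hist1h4i (chromosome 13, 22132829 to 22133231) share a chromosome, as do Polr2k (chromosome 15, 36103765 to 36106767) and Dcstamp (chromosome 15, 39577476 to 39592484). H2-Ob (chromosome 17, 34375850 to 34382853) and Lst1 (chromosome 17, 35322040 to 35325385) both lie in the major histocompatibility region. The coordinates span the first to the last exon of each gene.

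**Figure D1:**
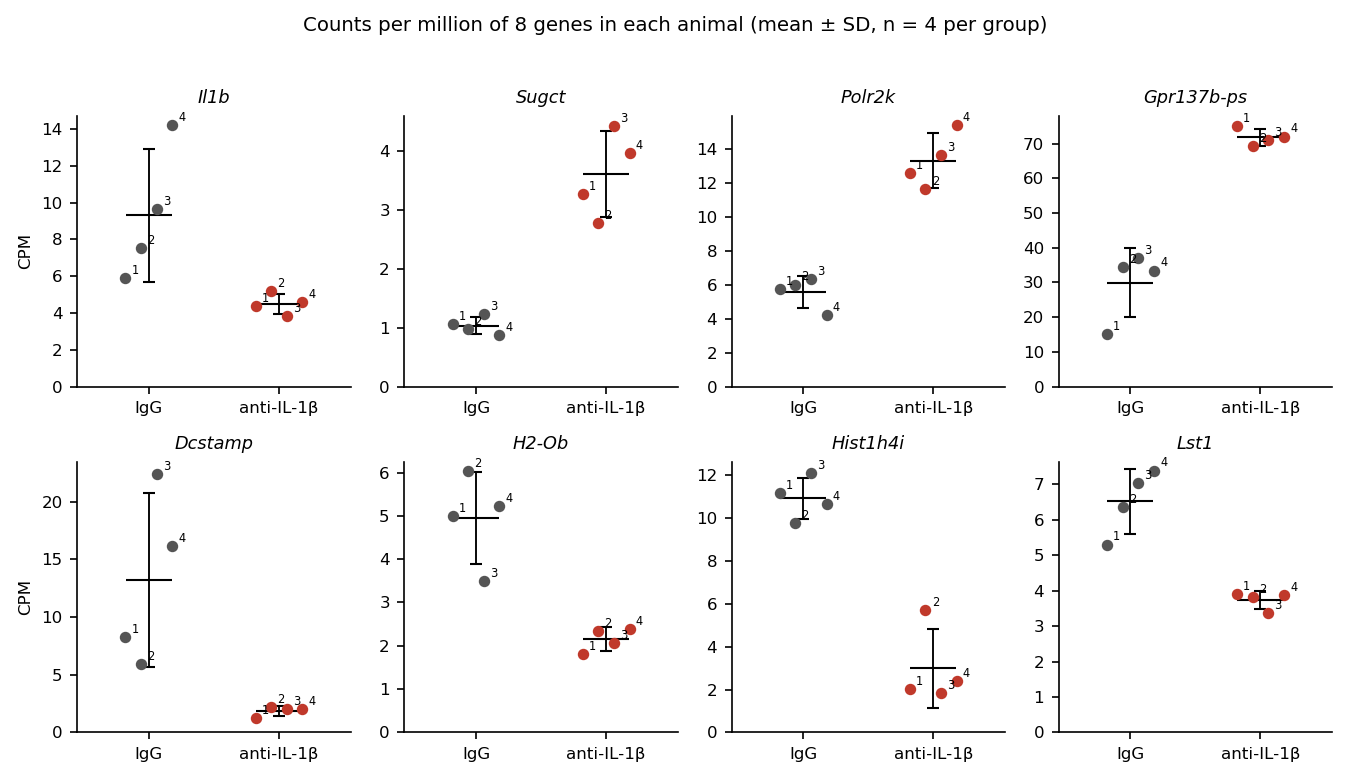
TMM-scaled CPM (vertical axes, from 0) of Il1b and 7 of the 10 genes with the smallest p, in each animal, with the animal's number beside its point and the group mean ± SD in black (n = 4 per group). In every panel the groups do not overlap; Dcstamp ranges from 5.95 to 22.4 CPM in IgG and from 1.27 to 2.17 CPM in antibody animals.

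Transcripts of the antibody's target were lower in treated lesions. Il1b (chromosome 2, 129190316 to 129196856) had 9.32 ± 3.61 CPM in IgG and 4.50 ± 0.551 CPM in antibody animals (SD, n = 4), and all 4 antibody values lay below all 4 IgG values. Its log2 fold change was -1.05 ± 0.26 (SE, 95% interval -1.64 to -0.46). Of the 13 panel genes, 1 (Il1b) passed 0.05 with edgeR when adjusted over the list alone (adjusted p = 0.0379), and 0 passed when adjusted over all genes (Il1b adjusted p = 0.9997, and 0.139 at the lowest under any alternative). Without IgG animal 1, 3 panel genes passed adjusted over the list alone. The call over the panel ended with the replicate number as a block (adjusted p = 0.107), with total-count scaling (0.0519), and without any 1 of IgG animals 3 and 4 and antibody animals 1 to 4 (0.0608 to 0.130); the Il1b fold change was negative under every alternative.

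The other panel genes did not pass. Il1a had a log2 fold change of -0.48 ± 0.40, Il1r1, the signalling receptor, -0.14 ± 0.16, and Il1rn, the receptor antagonist, -0.27 ± 0.32. Il6, an inflammatory cytokine gene induced by IL-1, had -0.59 ± 0.68. The smooth muscle contractile genes Acta2 (694 ± 215 CPM in IgG and 737 ± 393 CPM in antibody animals) and Myh11 had 0.09 ± 0.40 and 0.11 ± 0.31, with 95% intervals of -0.82 to 0.99 and -0.59 to 0.80. Col1a1 and Col3a1, the main fibrillar collagen genes, had -0.47 ± 0.33 and -0.52 ± 0.30. The macrophage genes Cd68 and Lgals3 had -0.27 ± 0.28 and -0.21 ± 0.32, and the alternative activation genes Arg1 and Mrc1 -0.22 ± 0.50 and -0.33 ± 0.22. Over all genes, the median half-width of the 95% interval was 0.40 on the log2 scale, and for 12951 genes (81.0%) the interval lay within 2-fold in either direction.

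Most members of several immune lists and of the proliferation list had fold changes below 0. Whether these lists passed depended on the correlation assumed between their genes. Other immune lists went the other way, with 7 of 8 mast cell, 4 of 5 thymocyte and all 16 interferon response genes higher. All 18 proliferation genes were lower (median log2 fold change -0.39), as were all 10 B and plasma cell genes (median -0.94), all 16 macrophage genes (median -0.34) and 28 of 29 IL-1 and NF-kB target genes (median -0.27). With camera and the preset correlation, 20 of 31 lists passed an adjusted p of 0.05, 15 lower and 5 higher. With an estimated correlation 0 lists passed in camera (smallest adjusted p = 0.315; 2 lists at an unadjusted p under 0.05), and with fry's test of a shared direction 0 passed (smallest adjusted p = 0.332; 2 at an unadjusted p under 0.05). Fry's mixed test, which counts change in either direction, passed 1 list, B and plasma cell genes (adjusted p = 0.0446). For the list scores per animal 0 lists passed (exact permutation test, smallest adjusted p = 0.732), and 1, proliferation, had an unadjusted p under 0.05. The estimated correlations between members had a median of 0.443 over lists, against the preset 0.01. Of the list members, 0 passed 0.05 with edgeR when adjusted over all genes, and 10, in 4 lists, passed when adjusted over the list alone. Without antibody animal 3 the camera count was 13 lists. With the macrophage score as a covariate it was 9, of which 6 were among the 20: proliferation (adjusted p = 3.731e-08), B and plasma cell (7.172e-09), alternative macrophage (0.00367), adventitial fibroblast (0.0101), cardiac muscle (0.0325) and epithelial and thyroid genes (0.00134). With 1 animal left out, the count of members past 0.05 adjusted over the list alone ranged from 2, without antibody animal 1 or 3, to 38, without IgG animal 1.

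The proliferation list had camera's smallest p (adjusted p = 1.328e-14; adjusted p = 0.398 with an estimated correlation). Its score was 3.50 ± 0.21 in IgG and 3.08 ± 0.22 in antibody animals (log2 CPM, SD, n = 4), the groups did not overlap, and the exact permutation p was 0.0286, the smallest possible. Mki67, the cell-cycle marker, had 66.7 ± 6.69 CPM in IgG and 45.4 ± 7.19 CPM in antibody animals and was the 1 member past 0.05 adjusted over the list alone (adjusted p = 0.0422, edgeR). Cenpf, Top2a and Bub1, all mitotic genes, had log2 fold changes of -0.53 ± 0.15, -0.65 ± 0.21 and -0.68 ± 0.24. The list passed camera with the preset correlation in all 22 alternatives that refitted it, and Mki67 passed over the list in 10 of 22.

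In the B and plasma cell list (camera adjusted p = 2.215e-09; adjusted p = 0.315 with an estimated correlation), Cd79b, Mzb1 and Jchain passed 0.05 adjusted over the list alone with edgeR (adjusted p = 0.00888, 0.00888 and 0.0319). Cd79b, a chain of the B cell receptor, had 2.84 ± 0.422 CPM in IgG and 1.35 ± 0.322 CPM in antibody animals. Mzb1 was near the floor, at 0.947 ± 0.382 CPM in IgG and 0.207 ± 0.139 CPM in antibody animals, with 2 to 10 counts per antibody library. Jchain, which joins secreted antibody molecules, had 20.9 ± 14.8 and 3.05 ± 3.22 CPM. Its groups overlapped, with 2.12 CPM in IgG animal 2 and 7.85 CPM in antibody animal 4. Ms4a1, which encodes CD20, had a log2 fold change of -1.91 ± 0.71. The list score was 1.43 ± 0.66 in IgG and 0.19 ± 0.60 in antibody animals (exact permutation p = 0.0571, n = 4). Of 22 alternatives, Cd79b and Mzb1 each passed over the list in 21 and Jchain in 16.

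Antigen presentation and dendritic genes were lower for 9 of 11 members (camera adjusted p = 9.780e-05; adjusted p = 0.412 with an estimated correlation). Ciita, the master regulator of class II genes, and H2-Aa, H2-Eb1, Cd74 and H2-Ab1, its targets, passed 0.05 adjusted over the list alone with edgeR (adjusted p = 0.0389 for the first 4 and 0.0430 for H2-Ab1). H2-Aa had 320 ± 81.1 CPM in IgG and 201 ± 34.4 CPM in antibody animals. Of 12 classical macrophage genes, 10 were lower (camera adjusted p = 9.888e-04; adjusted p = 0.412 with an estimated correlation), and the costimulatory gene Cd86 passed adjusted over the list alone (16.1 ± 2.79 and 9.15 ± 2.14 CPM, adjusted p = 0.0258, edgeR), with Cd80 at a log2 fold change of -0.74 ± 0.30. These single-gene calls depend on the alternatives: Cd86 passed over its list in 14 of 22, Ciita in 10 and the other 4 class II genes in 11. The general macrophage list (camera adjusted p = 1.816e-05; adjusted p = 0.570 with an estimated correlation) and the alternative list, with all 13 members lower (camera adjusted p = 7.574e-04; adjusted p = 0.412 with an estimated correlation), held 0 genes past either adjustment; Csf1r, the growth factor receptor of macrophages, had -0.38 ± 0.15 and F13a1 -0.43 ± 0.19. Without antibody animal 3 the alternative list had an adjusted p of 0.0543 (camera). With 1 surrogate variable the general (0.0628, mean log2 fold change -0.16 against -0.35) and classical lists (0.0781, mean -0.18 against -0.39) were lost. The macrophage score was 7.65 ± 0.47 in IgG and 7.34 ± 0.21 in antibody animals (exact permutation p = 0.286, n = 4), lowest in IgG animal 1 at 7.03.

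The IL-1 pathway lists passed camera with the preset correlation only. Of the 21 IL-1 ligands and receptors, 20 were lower (camera adjusted p = 6.052e-06; adjusted p = 0.412 with an estimated correlation), among them the inflammasome genes Pycard (-0.42 ± 0.14) and Nlrp3 (-0.42 ± 0.14). The IL-1 and NF-kB targets (camera adjusted p = 4.283e-06; adjusted p = 0.412 with an estimated correlation) included Birc3 (-0.33 ± 0.12), Nfkb2 (-0.36 ± 0.14) and the collagenase Mmp13 (-1.21 ± 0.46). In neither list did a member pass 0.05 adjusted over the list alone. The target score was 4.92 ± 0.40 in IgG and 4.58 ± 0.29 in antibody animals (exact permutation p = 0.2, n = 4). With the macrophage score as a covariate, neither list passed (adjusted p = 0.106 for ligands and receptors and 0.172 for targets, camera with the preset correlation). The same covariate ended the calls for antigen presentation (0.106), classical macrophage (0.196) and immediate early genes (0.106), among others, so the loss is not particular to IL-1 genes.

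The matrix lists, with small fold changes, also passed with the preset correlation only. In the collagen and matrix list 22 of 23 genes were lower, with a median log2 fold change of -0.21 (camera adjusted p = 0.00103; adjusted p = 0.570 with an estimated correlation), and Lox, the collagen cross-linking enzyme gene, had -0.49 ± 0.21. Of 15 matrix proteases 13 were lower (camera adjusted p = 0.0263; adjusted p = 0.579 with an estimated correlation), with Mmp3 at -0.70 ± 0.42. All 10 adventitial fibroblast genes were lower (camera adjusted p = 0.00771; adjusted p = 0.570 with an estimated correlation), with Dpp4 at -0.52 ± 0.28, as were 13 of 14 immediate early genes (camera adjusted p = 0.00120; adjusted p = 0.412 with an estimated correlation), with Zfp36 at -0.28 ± 0.12, and 11 of 12 unfolded protein response genes (camera adjusted p = 0.0493; adjusted p = 0.632 with an estimated correlation), with Creld2 at -0.28 ± 0.17. Several of these camera calls ended when a single animal was left out. In some of these fits the mean log2 fold change kept about its size. On all animals that mean was -0.23 for collagens, -0.29 for proteases, -0.14 for the unfolded protein response and -0.21 for adventitial fibroblast genes. Without IgG animal 3 the camera adjusted p was 0.0844 for collagens and matrix (mean -0.14), 0.796 for matrix proteases (mean -0.11) and 0.976 for the unfolded protein response (mean -0.02). Without antibody animal 3 it was 0.224, 0.178 and 0.0753 for the same lists (means -0.13, -0.23 and -0.15). For adventitial fibroblast genes it was 0.503 in that fit (mean -0.06). Matrix proteases were also lost without IgG animal 4 (0.2198, mean -0.20) or antibody animal 1 (0.0586, mean -0.26). Adventitial fibroblast genes were lost without IgG animal 1 (0.150, mean -0.13) or 4 (0.0526, mean -0.16). Unfolded protein response genes were lost without IgG animal 4 (0.273, mean -0.087) or antibody animals 1 (0.268, mean -0.095) or 2 (0.293, mean -0.099). With 1 surrogate variable the collagen (0.306, mean log2 fold change -0.078), protease (0.413, mean -0.16), unfolded protein response (0.636, mean -0.059) and immediate early lists (0.0534, mean -0.11) were lost. Without both IgG animal 2 and antibody animal 3 the collagen (0.683) and adventitial fibroblast lists (0.124) were lost.

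Smooth muscle lists did not pass. Of 16 contractile genes 11 were higher and 5 lower, with a median log2 fold change of 0.07 (camera adjusted p = 0.933), and Des, an intermediate filament gene, had 0.31 ± 0.17. The contractile score was 6.85 ± 0.14 in IgG and 6.87 ± 0.55 in antibody animals (exact permutation p = 0.971, n = 4). Of 13 modulated smooth muscle genes, which rise when these cells leave the contractile state, 11 were lower (median -0.22, camera adjusted p = 0.0886), with Klf4 at -0.16 ± 0.12 and Spp1 at -0.56 ± 0.47. That list passed as lower with DESeq2 (camera adjusted p = 0.0292), limma-voom (0.00174) and the other-tissue score as a covariate (0.0167), all at the preset correlation; with edgeR and an estimated correlation its adjusted p was 0.691. In the foam cell and lipid handling list 9 of 13 genes were lower (median -0.12, camera adjusted p = 0.956), with Cd36 at 0.31 ± 0.19 and Fabp5 at -0.49 ± 0.33. Without antibody animal 3 the contractile list passed as higher (camera adjusted p = 0.00131), and its mean log2 fold change was below 0 without antibody animal 2 (-0.11) or 4 (-0.01). The modulated list passed as lower without IgG animal 1 (0.00538), IgG animal 2 (0.0199) or antibody animal 4 (0.00486), had a mean of 0.04 without IgG animal 3, and the foam cell list passed as lower without IgG animal 1 (0.0129) and had a mean of 0.12 without IgG animal 3. With the macrophage score as a covariate, foam cell (camera adjusted p = 4.462e-05) and modulated smooth muscle genes (0.0325) passed as higher. All these list calls rest on the preset correlation; with an estimated correlation, run without any covariate and on all animals, the adjusted p was 0.998 for the foam cell and contractile lists and 0.691 for the modulated list.

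Higher lists were fewer, and in several a single animal carried the value. All 16 interferon response genes were higher (median log2 fold change 0.54, camera adjusted p = 0.00324; adjusted p = 0.579 with an estimated correlation), but antibody animal 3 had a score of 6.57, against 4.60 to 5.06 in the other antibody animals, and Ifit1 at 182 CPM. Without that animal the list's mean log2 fold change was -0.03 (camera adjusted p = 0.361). All 7 brown adipocyte genes were higher (camera adjusted p = 0.0322; adjusted p = 0.579 with an estimated correlation), with Cidea at 0.64 ± 0.24, and the mean without antibody animal 3 was -0.12 (camera adjusted p = 0.869). Nerve and Schwann genes were higher for 8 of 9 members (camera adjusted p = 0.00432; adjusted p = 0.440 with an estimated correlation), with S100b at 0.33 ± 0.16. Cholesterol synthesis genes were higher for 12 of 13 (camera adjusted p = 0.0322; adjusted p = 0.632 with an estimated correlation), and thymocyte genes for 4 of 5 (camera adjusted p = 0.0418; adjusted p = 0.520 with an estimated correlation) with a median of only 0.06. The nerve list was lost without IgG animal 3 (camera adjusted p = 0.349, mean 0.08 against 0.27 on all animals). The brown adipocyte call was also lost without IgG animals 1 (0.0816), 3 (0.115) or 4 (0.0938). Its mean there stayed at 0.44, 0.33 and 0.34, against 0.39 on all animals. The cholesterol list was lost without any 1 of IgG animals 2 to 4 and antibody animals 1 to 3 (0.0936 to 0.542). Its means there were -0.02 to 0.12, against 0.14 on all animals. The thymocyte list was lost without any 1 of IgG animals 2 to 4 and antibody animals 1 and 2 (0.0554 to 0.262). The means there were -0.76 to 0.13, against 0.04 on all animals. IgG animal 1 had a thymocyte score of 4.42, against -0.63 to 0.85 in the other IgG animals.

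Among markers of other tissues and cells, heart muscle genes came mainly from 1 IgG animal. All 7 cardiac muscle genes were lower with the antibody (median log2 fold change -2.43, camera adjusted p = 0.00771; adjusted p = 0.570 with an estimated correlation), and the score was 4.20 in IgG animal 2 against -0.25 to 0.43 in the other IgG animals; without that animal the adjusted p was 0.925. All 4 epithelial and thyroid genes were lower (camera adjusted p = 0.0151, and 0.412 with an estimated correlation), with Krt8 at -2.60 ± 1.06. Their mean log2 fold change was -1.21 on all animals. The call was lost without IgG animal 1 (camera adjusted p = 0.185, mean -0.67) or antibody animal 3 (0.0753, mean -1.03). Lists that did not pass were T cell (camera adjusted p = 0.0621), with Cd3g at -1.03 ± 0.39, cartilage and bone (0.121), with Ibsp at -0.83 ± 0.27, mast cell (0.124), white adipocyte (0.167), endothelial (0.373), erythroid (0.711), skeletal muscle (0.882) and neutrophil (0.997). The white adipocyte list had a mean log2 fold change just below 0 (-2.93e-04), a median of 0.24 and an upward camera direction, and the neutrophil list a mean of -0.04, a downward camera direction and a score difference of 0.01 in the other direction. Leaving out 1 animal brought a call for T cell genes as lower (0.00303 without IgG animal 3 and 0.00141 without antibody animal 2) and gave a mean of 0.12 without IgG animal 1; with the macrophage score as a covariate T cell genes also passed as lower (7.947e-04). The T cell score was highest in IgG animal 1 (3.08) and antibody animal 2 (2.76), against 1.32 to 2.02 in the other libraries. The thymocyte score was highest in the same animals (4.42 and 4.07). Antibody animal 1, with the next thymocyte score (2.75), had a T cell score of 1.66. Whether the T cell values follow the content of immature T cells was not tested. On all animals without a covariate the T cell list had an adjusted p of 0.599 with an estimated correlation. Leaving out 1 animal also brought calls for cartilage and bone (0.00910 without IgG animal 3, 0.0205 without antibody animal 2), mast cell (0.00155 without IgG animal 4, 0.0469 without antibody animal 4), endothelial (0.0407 without IgG animal 1), white adipocyte (0.0135 without antibody animal 2) and skeletal muscle genes (0.0440 without antibody animal 3). These calls used the preset correlation; on all animals the adjusted p with an estimated correlation was 0.570 for cartilage and bone and for white adipocyte, 0.579 for mast cell, 0.790 for endothelial and 0.998 for skeletal muscle genes.

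**Figure D2:**
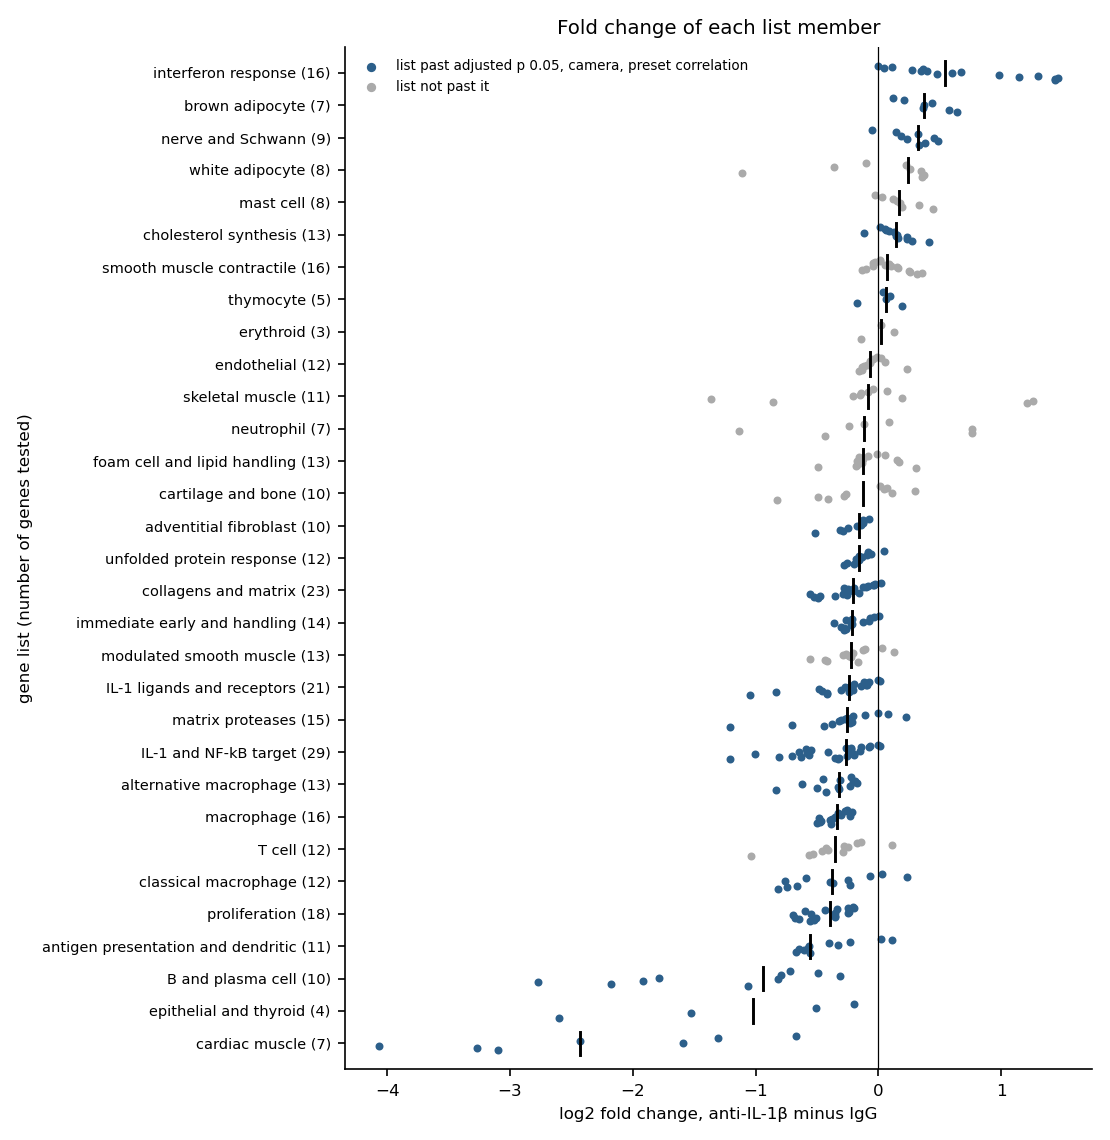
Log2 fold change (horizontal axis, antibody minus IgG) of every kept member of the 31 lists, with the list median as a black bar and the number of genes in brackets; blue lists passed camera's adjusted p of 0.05 with the preset correlation. The proliferation, macrophage and B and plasma cell members all lie below 0, and interferon response members all above it.

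**Figure D3:**
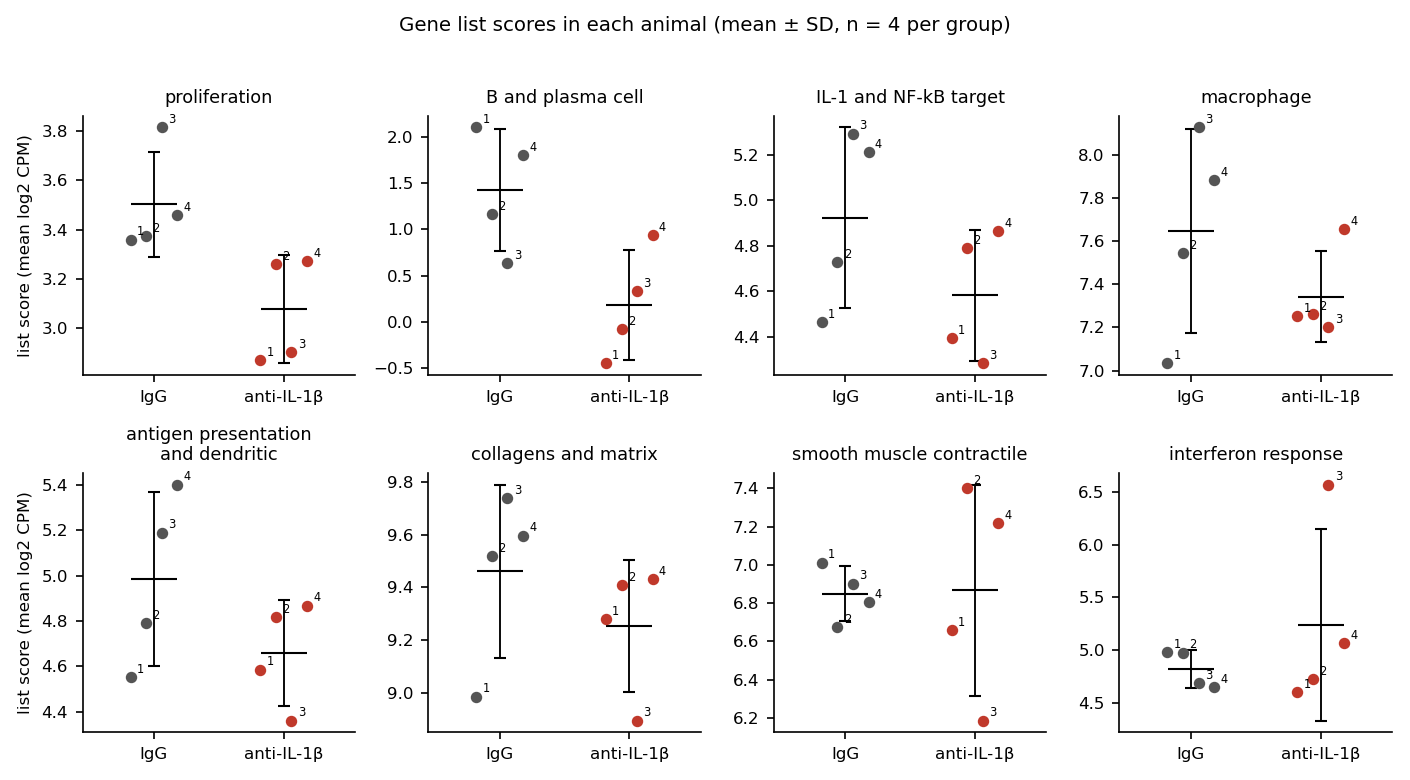
Mean log2 CPM of the members of 8 lists in each animal (vertical axes do not start at 0), with the animal's number beside its point and the group mean ± SD in black (n = 4 per group). Only proliferation, of these 8, has groups that do not overlap, and antibody animal 3 stands alone in the interferon panel at 6.57.

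Across all kept genes the groups did not separate along the largest axis of variation. Principal component 1 held 35.9% of the variance, with scores of 11.5 ± 37.4 in IgG and -11.5 ± 21.4 in antibody animals (SD, n = 4, exact permutation p = 0.314), and component 2 held 23.4% (exact permutation p = 0.8286). Spearman correlations between libraries, taken across genes, which are not independent replicates, ranged from 0.9599 to 0.992.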

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

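The test of heart muscle in the sample, the rank of the IL-1 and NF-kB target score in antibody animal 3, and the interval and slope with the macrophage score in the model, were chosen only after the results were seen. A value far from the other 3 of its group was found in 10 of 122 groups of 4, where chance gives about 6.1 (about 1 in 20).

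Most members of the macrophage, IL-1 and NF-kB target, B and plasma cell and proliferation lists had fold changes below 0 in antibody animals. Antibody animal 4 had a macrophage score of 7.65 against 7.20 to 7.26 in the other antibody animals. With the macrophage score in the model, the difference in the IL-1 and NF-kB target score went from -0.34 to -0.085 (exact permutation p of the residuals 0.543), which is consistent with fewer macrophages in the sample as a source of that part. For B and plasma cell genes it went from -1.24 to -1.39 (95% interval -2.71 to -0.06) and the score did not follow the macrophage score (slope -0.47 ± 0.74, SE). The interval and slope argue against fewer macrophages as the whole source. The rule fixed beforehand asked for an exact permutation p of the residuals under 0.05. That p was 0.0857, so by the fixed rule the question stays undecided. The list's camera call (adjusted p = 7.172e-09 with this covariate) rests on the preset correlation (without the covariate, adjusted p = 0.315 with an estimated correlation). For proliferation the score difference went from -0.43 to -0.30 (95% interval -0.64 to 0.04, exact permutation p of the residuals 0.0857). That list passed camera at the preset correlation only (adjusted p = 3.731e-08, and without the covariate 0.398 with an estimated correlation). Macrophage content and other sources therefore cannot be told apart there with 4 animals per group. Fewer macrophages could be an effect of the antibody or of which part of the vessel was taken, and neither was tested.

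The cardiac muscle score was 4.20 in IgG animal 2 against -0.25 to 0.43 in the other IgG animals, and the same library had 21902802 assigned counts against 28747515 to 29453014 and an assigned share of 24.4% against 33.2% to 34.9%. Genes of the same mean level (1009 genes) had a median log2 difference of 0.10 from the other 7 libraries, against 4.15 for the cardiac list, which argues against lower depth as the source. Of 16 further cardiac genes 9 (56.3%) were over 2-fold higher, with a median log2 difference of 1.30, so heart muscle in the sample may be the source but remains open. Explanations other than depth and heart muscle in the sample were not tested.

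The interferon score was 6.57 in antibody animal 3, which was looked at although it is not among the 10 far values. The IL-1 and NF-kB target score of this animal was 4.28, rank 1 of 8 from the lowest. This cannot decide on a general inflammatory state, because the animal had been given the antibody against IL-1β. Genes of plasmacytoid dendritic cells (7 genes) had a median log2 difference of -0.20 from the other libraries, against 1.72 for the interferon list. Those markers were therefore not higher as a set. The test cannot decide on those cells as the source, because it asks only whether their markers rose as much as the interferon genes. Runx2, 1 of the 7, is also in the cartilage and bone list. Of 18 further interferon genes 11 (61.1%) were over 2-fold higher, with a median log2 difference of 1.10, so a coordinated response may be present but was not decided. An infection or another event in this animal was not tested.

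The cartilage and bone score was 3.94 in antibody animal 2 against 3.44 to 3.52 in the others of its group. Gpr137b-ps had a log2 CPM of 3.92 in IgG animal 1 against 5.06 to 5.21. Dcstamp had a log2 CPM of 0.43 in antibody animal 1 against 1.06 to 1.17. Lst1 had a log2 CPM of 1.79 in antibody animal 3 against 1.96 to 1.99. Col3a1 had a log2 CPM of 11.03 in IgG animal 1 against 12.23 to 12.42. IgG animal 1 had a score of 24.7 on principal component 4 against -1.16 to 0.929.

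The 8 libraries can be parted into 4 and 4 in 35 ways. The real grouping gave 0 genes past an adjusted p of 0.05 with edgeR (509 at an unadjusted p under 0.05; DESeq2 8 and limma-voom 2), which all 35 match by construction, so that comparison says nothing about chance; the highest other count was 596. For genes at an unadjusted p under 0.05, 18 of 35 gave as many as the real 509, the highest other being 3558. For lists past camera's adjusted p with the preset correlation, 3 of 35 gave as many as the real 20, the highest other being 22. Chance can therefore not be excluded for the count at an unadjusted p or for the count of lists. The split with 596 genes put IgG animals 2, 3 and 4 with antibody animal 4, the 4 libraries with the highest macrophage scores. It is the real grouping with IgG animal 1 and antibody animal 4 exchanged. It also parts the libraries by the sign of principal component 1. As the highest of 35 splits it was picked after the fact, so its gene count is not a test of that split. Principal component 1, taken without the group labels, held 35.9% of the variance. Its scores were -40.1 to -14.1 in IgG animal 1 and antibody animals 1 to 3, and 8.13 to 40.5 in the others. The largest axis of variation therefore did not follow the groups, and its source was not tested.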

How the results depend on the processing

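The alternatives without both IgG animal 2 and antibody animal 3, and with the macrophage score as a covariate, were chosen only after the data had been seen; the others were fixed beforehand. In the text below, gene values are log2 fold changes, list values are mean log2 fold changes, and where a value differed in sign or call the cause was not tested unless stated. Of all values under alternatives, 1109 kept direction and call, 100 lost a call, 34 gained a call, 36 counts or values without a test moved and 92 reversed.

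The count of genes past the threshold was 0 with edgeR (509 at an unadjusted p under 0.05), 8 with DESeq2, 2 with limma-voom and 0 to 1 with 1 animal left out; the same counts, 8, 2 and 0 to 1, hold for the named genes. Panel genes past 0.05 adjusted over the list alone numbered 1 with edgeR, 3 with limma-voom, 0 to 3 with 1 animal left out, and 0 with total-count scaling, either block, the surrogate variable, the macrophage score as a covariate, and without both libraries. List members past 0.05 adjusted over the list alone numbered 10, and 19 with DESeq2, 74 with limma-voom, 4 with total-count scaling, 5 with the other-tissue score, 3 without both libraries and 2 to 38 with 1 animal left out. Lists past the threshold numbered 20, and 11 with the surrogate variable, 9 with the macrophage score, 0 with an estimated correlation, 0 with fry's directional test and 13 to 22 with 1 animal left out. Il1b stayed negative throughout, between -1.48 and -0.75.

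With the replicate block, which adds the replicate number to the model, 20 lists passed, all 20 shared with the fit without it, and edgeR again called 0 genes (361 at an unadjusted p under 0.05). Values that reversed with the replicate block were Acta2 (-0.033), Arg1 (0.070), and the neutrophil (0.011) and white adipocyte (0.085) lists. With replicates 1 and 2 against 3 and 4 as a block, only the white adipocyte list did (0.052). The replicate numbers do not pair the animals: the own number gave the closest match for 2 of 8 libraries.

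With 1 surrogate variable the reversed values were Il6 (0.14), Lgals3 (0.049) and the cholesterol synthesis (-0.13), endothelial (0.077), erythroid (-0.17), foam cell (0.10), skeletal muscle (0.082) and white adipocyte (0.017) lists, and the calls lost were those for cardiac muscle (adjusted p = 0.312), nerve and Schwann (0.0869), thymocyte (0.489), collagen, protease, macrophage, classical macrophage, immediate early and unfolded protein response genes. With limma-voom the reversed values were Acta2 (-0.18), Arg1 (0.063) and the cardiac muscle (0.0091), endothelial (0.046), mast cell (-0.12), skeletal muscle (0.66, passing as higher with adjusted p = 0.0292) and white adipocyte (0.083) lists, and the erythroid list passed as higher (0.0300). The erythroid list, of 3 genes, reversed with DESeq2 (-0.0053), DESeq2-type size factors (-0.0061), upper-quartile factors (-0.00999) and no filter on low counts (-0.011), and the last also reversed the neutrophil list (0.16). Total-count scaling reversed the skeletal muscle (0.034) and white adipocyte (0.015) lists and raised the share of higher genes among those at an unadjusted p under 0.05 from 35.4% to 53.1%; it was 57.4% of 1517 genes without IgG animal 1 and 54.9% of 783 without antibody animal 2.

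With the other-tissue score as a covariate the reversed lists were endothelial (0.0041), skeletal muscle (0.56) and white adipocyte (0.023). With the macrophage score as a covariate the genes Cd68 (0.21), Il1a (0.30), Il1r1 (0.017), Il1rn (0.26), Il6 (0.58) and Lgals3 (0.33) reversed, and so did the lists for cholesterol synthesis (-0.18), endothelial (0.022), erythroid (-0.31), foam cell (0.23), matrix proteases (0.033), modulated smooth muscle (0.15), unfolded protein response (0.060) and white adipocyte (0.024). Of these, foam cell (adjusted p = 4.462e-05) and modulated smooth muscle genes (0.0325) passed as higher; T cell genes, which kept their direction, passed as lower (7.947e-04), as they did with DESeq2 (0.0247), total-count scaling (0.0402) and the surrogate variable (4.677e-04). Calls gained under alternatives were tested with the preset correlation only. Cartilage and bone genes passed as lower with the stricter filter (0.0335), and modulated smooth muscle genes passed as lower with DESeq2 (0.0292), limma-voom (0.00174) and the other-tissue score (0.0167). The collagen (-0.014) and macrophage (-2.352e-04) lists kept a mean below 0 with the macrophage score and an upward camera direction; for the macrophage list the covariate removes the difference by construction.

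Without both libraries the reversed lists were brown adipocyte (-0.026), cardiac muscle (0.077), cholesterol synthesis (-0.072), endothelial (0.058), erythroid (-0.047), neutrophil (0.16), skeletal muscle (1.02) and thymocyte (-0.024), and the interferon list (0.049) had a downward camera direction. Skeletal muscle (adjusted p = 4.321e-05) and smooth muscle contractile genes (0.0170) passed as higher there. These libraries carried the cardiac and interferon values.

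With 1 animal left out, the ranges were -0.94 to 0.087 for Il6, -0.17 to 0.35 for Acta2, -0.16 to 0.32 for Myh11, -0.47 to 0.0031 for Cd68, -0.41 to 0.13 for Lgals3 and -0.56 to 0.089 for Arg1. For lists they were -0.11 to 0.26 for smooth muscle contractile, -0.36 to 0.041 for modulated smooth muscle, -0.21 to 0.12 for foam cell, -0.18 to 0.17 for neutrophil, -0.82 to 0.12 for T cell, -0.76 to 2.74 for thymocyte and -0.12 to 0.050 for endothelial genes. They were -0.095 to 0.17 for white adipocyte, -0.12 to 0.56 for brown adipocyte, -0.41 to 0.67 for skeletal muscle, -0.22 to 0.44 for erythroid, -0.025 to 0.88 for interferon response and -0.016 to 0.64 for cholesterol synthesis genes.

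The proliferation list passed with the preset correlation in 22 of 22 alternatives and the B and plasma cell list in 21 of 21, while the thymocyte list passed in 9 of 21 and cholesterol synthesis in 10 of 22. Both of the former calls are lost with an estimated correlation (adjusted p = 0.398 for proliferation and 0.315 for B and plasma cell genes) and with fry's directional test (0.332 for both). With 4 animals per group and these depths, the simulated data gave calls for 54% of genes changed 2-fold and 16.3% of genes changed 1.5-fold, so changes of that size in single genes were often not detectable.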

Other observations

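Both tests of chromosome position were chosen only after the positions of the genes with the smallest p had been seen. Several of those genes lie on chromosomes 13, 15 and 17, and a candidate explanation is stretches of chromosome with different alleles in the groups. Of the 50 genes with the smallest p, 12 lay within 2 Mb of another, and 11 of 35 splits of the libraries gave as many (highest other 17; median of the others 7.5; median of 10000 random sets 6). Without histone and H2 genes the count was 6, and 30 of 35 splits gave as many (highest other 17), but neither count decides. Of the 7 named genes that share a chromosome, only H2-Ob and Lst1 lie within 2 Mb of another, and leaving out H2 genes breaks that pair. Those on chromosome 13 and chromosome 15 lie farther apart, wider stretches were not tested, and the explanation stays open.

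Genes of immature T cells were high in some animals of both groups. Rag1, which cuts receptor genes in developing lymphocytes, had 46.3 CPM in IgG animal 1, 38.8 in antibody animal 2 and 7.61 in antibody animal 1, and Dntt had 11.8, 7.82 and 2.29 CPM in the same libraries. The thymocyte scores in these animals were 4.42, 4.07 and 2.75, and the list's score difference between groups was 1.33 (exact permutation p = 0.314).

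The brown fat gene Ucp1 had 3060 CPM in antibody animal 3, and the fat synthesis gene Scd1 took 3.86% of assigned counts in IgG animal 1. Neither was confined to that animal: Ucp1 had 1043 ± 210 CPM in IgG animals (SD, n = 4), and Scd1 took 1.66% or more of counts in every library. The adipocyte gene Adipoq had 176 to 405 CPM over the 8 libraries. Fat cell genes were therefore read in every library, so expression values here cannot be assigned to lesion cells alone. Apoe, the apolipoprotein E gene, had 25.0 ± 5.32 CPM in IgG and 15.1 ± 2.03 CPM in antibody animals (SD, n = 4), with a log2 fold change of -0.72 ± 0.17 that did not pass in edgeR (adjusted p = 0.9997). Its counts were low, 268 to 793 per library, and the labels do not state whether the Apoe gene is intact in these mice, so whether the reads come from an intact gene is not known. It was singled out after its values were seen.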
